A study of Danio rerio with 6 samples.

How the data were processed

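Retinal RNA of 3 wild-type and 3 samd7 mutant fish was profiled by paired-end sequencing of 150 bp reads. Per the labels' protocols, cDNA was made from 10 ng of RNA with a SMARTer kit and 12 cycles of amplification, and libraries with 15 cycles of PCR. The submitters' processing notes list Trim Galore 0.6.1, STAR 2.7.2b, HTSeq 0.9.1, DESeq2 1.34.0 and R 4.1.3 and the zebrafish build danRer10, without their settings. The strand setting and the annotation version are not given in the sources used here.

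The authors deposited one table of 14781 genes. Its signal values, as deposited, are read counts per gene that the authors divided by one size factor per library. Every value of a library was a whole multiple of one step within a tolerance of 0.01 reads, so whole reads were recovered. The size factors, 0.863 to 1.18, were equal to median-ratio factors recomputed from those reads. The authors also deposited log2 fold changes of mutant over wild type and an adjusted p value per gene, per the file headers. The log2 and p values of the authors were only counted and compared, and each test below was computed here. Gene names were used as the table gives them. Of these 12660 were current symbols and 1848 synonyms in the RefSeq table of assembly GRCz12tu with 49597 genes, which was used for names and neighbours only. Of all names, 11 looked like dates and were left as they were.

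Samples were grouped by the genotype in the labels. The main test was limma 3.58.1 in R 4.3.3 with a mean-variance trend and robust variance moderation, on log2(value + 1) of the deposited values. Genes needed a value of at least 10 in at least 3 libraries, which left 11335, and 1037 were at 0 in all 6. The threshold was a Benjamini-Hochberg adjusted p of 0.05. The choices of test, gene lists, named genes and alternatives were made before the data were examined, except where stated. The 33 gene lists held 1048 entries, of which 882 were in the table, and the 32 lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01, with adjustment over the lists. Camera with an estimated correlation and fry, which tests whether genes of a list move one way on balance, were alternatives. Opsin shares were compared by exact two-sided permutation tests, whose smallest p with 3 against 3 is 0.1. Genes near 0 were those under 0.1 CPM in each library of one genotype and over 1 CPM in each of the other, on the deposited values rescaled to CPM.

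Genes were named by a fixed rule. It took samd7, all visual opsins, and the 12 largest log2 changes in each direction among genes past the threshold without overlap of the genotypes, with a mean of at least 1 CPM and a gene symbol. To these it added up to 4 genes with the smallest p of each list discussed. For genes at 0 in a genotype a floor of 3 reads per library was used, and for those with few reads 95% Poisson intervals.

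The tools were tested on simulated counts for the comparison of mutant and wild type, with 200 genes changed. On 11220 genes limma recovered 38% of 2-fold and 76% of 4-fold changes, with 13 false among 127 calls. The quasi-likelihood test of edgeR 4.0.16 recovered 41% and 78%, with 11 false among 130. On 11339 genes DESeq2 1.42.0 recovered 61% and 86%, with 51 false among 198. On 11223 genes with no change simulated, limma called 0 genes and camera 0 of 32 lists. With a change put into the cell cycle list, on top of the 200 changed genes, camera called that list and 0 others. Genes were simulated independently of one another, so these runs cannot show how often camera calls lists whose genes move together.

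No pair of libraries of a genotype was a copy of another, as the read counts of each pair differed by a chi-square per degree of freedom of 58.7 or more. Pearson correlations of log2 values across genes, which are not independent replicates, were 0.958 to 0.972 within wild type, 0.972 to 0.978 within the mutants and 0.939 to 0.961 between them. The alternatives tried were median-ratio, TMM, library-total and upper-quartile scaling, 2 other filters, pseudocounts of 0.1 and 10, limma without trend, DESeq2, voom, edgeR (chosen after the data were seen), a replicate block, stricter thresholds and each library left out in turn. Shares of opsins by transcript length were not analysed here.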

Results

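The data were RNA-seq profiles of adult zebrafish retina from 3 wild-type fish and 3 fish homozygous for a mutation in samd7, a gene for a SAM-domain protein of photoreceptors that acts with Polycomb repressive complexes. All fish were males of 3 months from a cross between heterozygotes. Each library came from both retinas of 1 fish, so that replicates were separate animals. The title of the series concerns photoreceptor identity and the expression of one opsin per photoreceptor, and the design gives one comparison, mutant against wild type. The deposited values were read counts per gene divided by a size factor per library, called normalised read counts here. The wild-type libraries held 29117026, 22529193 and 22777234 reads in genes, and the mutant libraries 20186266, 20653051 and 24352510. Between 12691 and 12876 genes had a read in each library. Values below are means ± SD of the normalised read count with n = 3 fish per genotype. Log2 changes are mutant minus wild type on the log2(value + 1) scale. Adjusted p is from limma, with Benjamini-Hochberg adjustment over 11335 genes, unless another test is named.

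The samd7 transcript itself was at 4646 ± 501 in wild type and 3745 ± 1328 in the mutants (log2 change -0.37, SE 0.26, adjusted p = 0.466). This difference was within the spread of the mutants, which held 2471, 5121 and 3642. The wild-type libraries held 4196, 4557 and 5186, so the level of the transcript did not check the genotype labels.

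Green cone opsins and the red cone opsin opn1lw2 fell steeply in the mutant retinas, and the UV opsin rose. The 4 green cone opsins opn1mw1, opn1mw2, opn1mw3 and opn1mw4 together were at 256691 ± 120018 in wild type and 23.9 ± 20.5 in the mutants. The red cone opsin opn1lw2 fell from 156681 ± 74991 to 4206 ± 608, 37.2-fold (log2 change -5.10, SE 0.37, adjusted p = 0.00390). Its tandem copy opn1lw1 was at 148923 ± 102989 and 50451 ± 17324 and did not pass the test (log2 change -1.18, SE 0.79, adjusted p = 0.448). Without wild-type replicate 1, which held 30002 against 207990 and 208775 in wild-type replicates 2 and 3, opn1lw1 was called lower (log2 change -2.11, adjusted p = 0.0343). The UV cone opsin opn1sw1 was 3.02-fold higher, at 165581 ± 32279 in wild type and 499547 ± 73130 in the mutants (log2 change 1.60, SE 0.20, adjusted p = 0.0198). The blue cone opsin opn1sw2 was at 269289 ± 63218 and 511834 ± 94525, which missed the threshold (log2 change 0.94, SE 0.23, adjusted p = 0.0871). It passed in 4 of 20 alternatives, among them library totals as the scaling (adjusted p = 0.0225), DESeq2 (0.00216) and a replicate block. Over all alternatives its adjusted p was between 0.00216 and 0.289. For opn1sw1 and opn1sw2 all 3 mutants lay above all 3 wild-type fish.

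Each green opsin fell by itself, with adjusted p between 0.000574 for opn1mw1 and 0.00695 for opn1mw4. No read of opn1mw1 was counted in any mutant library, against 528 ± 236 normalised reads in wild type, which made it at least 187-fold lower at a floor of 3 reads per library. For opn1mw3, 2 reads were counted over the 3 mutant libraries, a ratio of 134409 with a 95% Poisson interval of 41325 to 1232670. For opn1mw4, 10 reads in the mutants gave a ratio of 8718 (4259 to 16333). For opn1mw2, 61 reads gave a ratio of 6777 (5601 to 9406). These intervals and floors leave out the spread between fish, since the wild-type mean was held fixed and the intervals pool the mutant reads. For example, the mutant libraries held 9, 43 and 9 reads of opn1mw2. Counting error is not fully covered either, as PCR copies are not independent molecules. In the RefSeq table of the GRCz12tu assembly the 4 green opsins are adjacent to one another, and opn1lw1 lies between the microRNA gene mir726 and opn1lw2. Such copies are similar in sequence, so the division of reads between them is uncertain, and their sums carry more weight than the single copies. Positions are not given because the deposited counts were made on the danRer10 build.

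**Figure D1:**
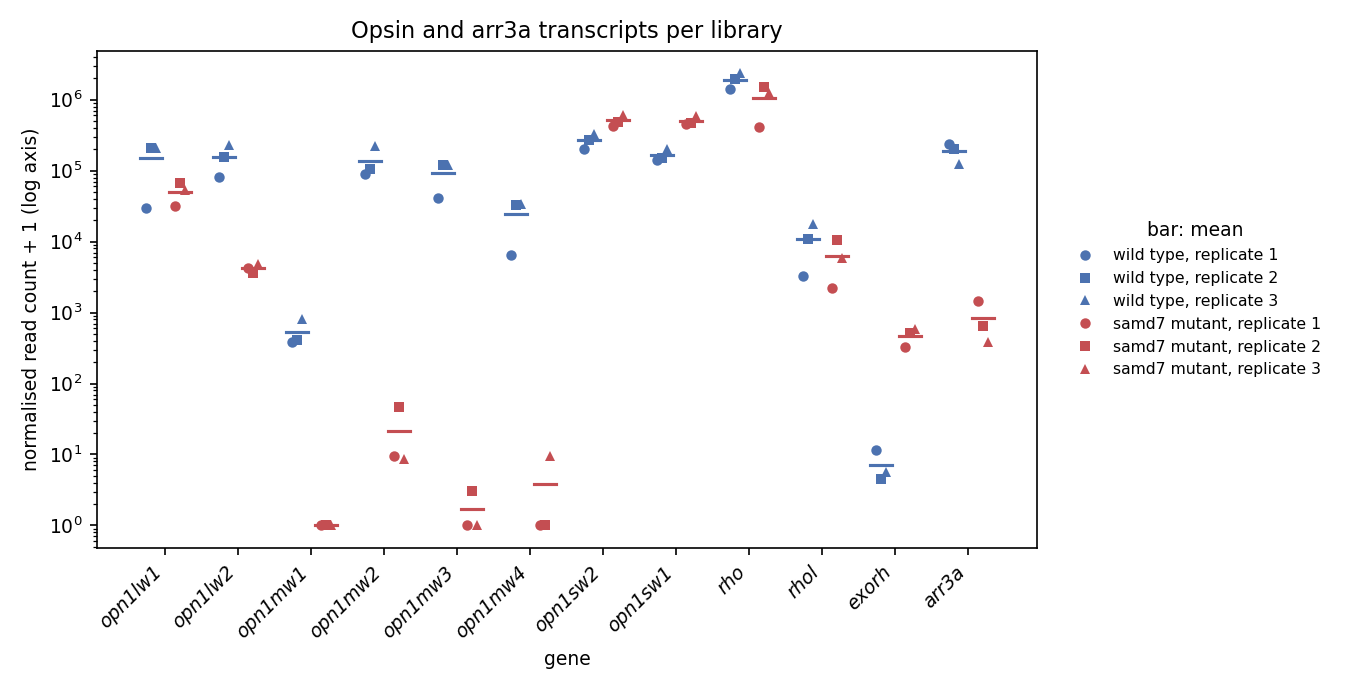
Normalised read count plus 1 (log axis) of 10 visual opsins, the pineal opsin exorh and the cone arrestin arr3a in each library, with wild type in blue, samd7 mutants in red, symbols for the replicates and bars for the means. The 4 green opsins (opn1mw1 to opn1mw4) lie near 0 in the mutants, opn1lw2 and arr3a are far lower, and exorh and opn1sw1 are higher in all 3 mutants.

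The cone opsins differed in composition, while their totals overlapped. The summed cone opsins were 997165 ± 380205 in wild type and 1066060 ± 174579 in the mutants, a ratio of 1.07 (exact permutation test, two-sided, p = 1). In wild type, opn1sw1 made up 17.8 ± 5.28% of the cone opsins, opn1sw2 28.3 ± 5.26%, opn1lw2 15.3 ± 1.73% and opn1mw2 13.7 ± 3.32%. In the mutants opn1sw1 made up 47.0 ± 1.71% and opn1sw2 47.9 ± 0.964%, with opn1lw1 at 4.72 ± 1.55% and opn1lw2 at 0.398 ± 0.0634%. The genotypes did not overlap in the shares of opn1sw1, opn1sw2, opn1lw2 and opn1mw2, and an exact two-sided permutation test gave p = 0.1 for each, the smallest that 3 against 3 can give. Adjusted over the 18 shares tested, this was 0.12. The shares of a library are tied, so the fall of green and red opsins by itself raises those of opn1sw1 and opn1sw2. Their shares alone thus do not show that either opsin rose. The ratio of opn1sw1 to opn1sw2 was 0.622 ± 0.0711 in wild type and 0.981 ± 0.0487 in the mutants, and the log2 ratio of opn1lw1 to opn1lw2 was -0.40 ± 0.95 and 3.53 ± 0.67, each with p = 0.1 in the same exact test.

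The rod opsin rho was at 1917730 ± 467517 in wild type and 1043510 ± 563409 in the mutants (log2 change -1.05, SE 0.50, adjusted p = 0.297). Its paralog rhol was at 10716 ± 7350 and 6180 ± 4144 (log2 change -0.74, SE 0.79, adjusted p = 0.640). The call of the UV opsin gene opn1sw1 was lost without wild-type replicate 2 (adjusted p = 0.0984), without mutant replicate 1 (0.0838), without mutant replicate 3 (0.114) and with limma without trend (0.0531). That of opn1mw4 was lost with voom (0.0649). The calls of opn1mw2 and opn1lw2 held without each library in turn (adjusted p up to 0.0470). Without a wild-type library, opn1mw1, opn1mw3 and opn1mw4 no longer met the filter and were not tested.

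Genes that mark red and green cones were lower with their opsins, and those of blue and UV cones were higher. The cone arrestin arr3a fell from 188635 ± 59498 to 825 ± 547 (log2 change -7.99, SE 0.50, adjusted p = 0.00324). The thyroid hormone receptor thrb, needed for red cone fate, fell from 4079 ± 1005 to 841 ± 237 (log2 change -2.28, SE 0.27, adjusted p = 0.0200). The red and green cone list fell as a group (camera, adjusted p = 5.02e-15; adjusted p = 0.0852 with an estimated correlation). Of its 11 members 7 were lower over all genes tested, namely 5 opsins, arr3a and thrb, and 10 were lower when adjusted over the list alone. Its median log2 change was -5.10, the same with opn1mw1 at its bound. The blue and UV cone list was higher (camera, adjusted p = 2.10e-05; adjusted p = 0.230 with an estimated correlation; median log2 change 0.84). Of its 8 members 4 rose over all genes and 6 when adjusted over the list alone. Next to opn1sw1 these were skor1b (log2 change 1.54), tbx2a (0.96) and tbx2b (0.63), the T-box factor that UV cone fate requires.

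Of 26 tested photoreceptor transcription factors 3 rose and 3 fell, and the list had no common direction (camera, adjusted p = 0.558). The repressor prdm1a rose 5.45-fold (adjusted p = 0.0319), next to tbx2a and tbx2b. With thrb, the rod factor nrl fell to 0.386 of wild type (adjusted p = 0.0408), and so did mef2cb, chosen after its values were seen (log2 change -0.88, adjusted p = 0.0422). Adjusted over the list alone, 6 of these factors rose and 6 fell. The call of thrb was lost without wild-type replicate 2 (adjusted p = 0.0918), mutant replicate 1 (0.0693) or mutant replicate 3 (0.111). Those of nrl, prdm1a, skor1b, tbx2a, tbx2b and mef2cb were lost without these and also without wild-type replicate 3, with adjusted p of up to 0.184 for mef2cb and 0.178 for nrl. Without mutant replicate 2 those of tbx2a (0.0521) and mef2cb (0.0789) were lost, and without wild-type replicate 1 that of tbx2a (0.0573).

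Cone phototransduction genes were lower as a group (camera, adjusted p = 1.40e-08; adjusted p = 0.157 with an estimated correlation; median log2 change -1.27). Of 20 tested members 6 fell and none rose, and adjusted over the list alone 14 fell and 1 rose. The cone exchanger gene slc24a2 fell from 22577 ± 1552 to 6990 ± 609 (log2 change -1.69, adjusted p = 0.00324). The cone transducin gnat2 fell from 245293 ± 37617 to 108361 ± 6098 (log2 change -1.17, adjusted p = 0.0244), and guca1d, a guanylate cyclase activator, by 6.50-fold (adjusted p = 0.0244). The visual opsin list was also lower (camera, adjusted p = 2.10e-05; adjusted p = 0.398 with an estimated correlation). Of its 10 genes 5 fell and 1 rose, or 5 and 2 when adjusted over the list alone. The 5 that fell are also in the red and green cone list, as is arr3a of the cone phototransduction list. These list calls are therefore not independent. The call of the visual opsin list was lost without wild-type replicate 2 (camera, adjusted p = 0.188) and without wild-type replicate 3 (0.311). The calls of arr3a and slc24a2 held without each library in turn. Those of gnat2 and guca1d were lost without wild-type replicate 2 (adjusted p = 0.0923 and 0.0984), wild-type replicate 3, mutant replicate 1 or mutant replicate 3 (0.153 and 0.0535).

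Rod genes were lower as a list but hardly one by one. The rod phototransduction list had a median log2 change of -1.01 over 21 genes, 20 of them negative (camera, adjusted p = 3.03e-05; adjusted p = 0.527 with an estimated correlation and 0.246 with fry). Only nrl fell, over all genes and also when adjusted over the list alone. The arrestin saga was at 34566 ± 9054 and 15445 ± 9035 (adjusted p = 0.165), and guca1b at 10188 ± 1331 and 5348 ± 2868 (adjusted p = 0.207). The mutants differed among themselves, since rho took 2.18% of the reads in mutant replicate 1, 6.90% in replicate 2 and 5.97% in replicate 3, against 5.58%, 7.60% and 8.98% in wild type. Relative to the mean of all libraries, the rod list stood at -1.46, 0.31 and -0.36 on the log2 scale in mutant replicates 1, 2 and 3, and between 0.39 and 0.59 in wild type.

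Outer segment and cilium genes fell as a list (camera, adjusted p = 5.62e-10; adjusted p = 0.230 with an estimated correlation; median log2 change -0.64). Of its 26 genes 7 fell, and 14 when adjusted over the list alone. Among them were rp2, whose human counterpart is mutated in retinitis pigmentosa (log2 change -0.77, adjusted p = 0.0388), the disc rim genes prph2a (-0.73, adjusted p = 0.0388) and prph2l (-0.73, adjusted p = 0.0420), and the fascin fscn2a (-1.13, adjusted p = 0.0389). Photoreceptor synapse genes were lower too (camera, adjusted p = 0.00101; adjusted p = 0.314 with an estimated correlation and 0.112 with fry; median log2 change -0.41). Of the 17 tested, the complexin cplx4a fell (log2 change -0.96, adjusted p = 0.0362), and adjusted over the list alone 9 fell and 1 rose. With library totals as the scaling, 18 of the 26 outer segment genes had a negative change in place of 25, and the median of the synapse list was -0.060. The gene calls of this paragraph were lost without wild-type replicate 2 (rp2, adjusted p = 0.133), mutant replicate 1 (0.155) or mutant replicate 3 (0.178). Those of prph2a (0.0892), prph2l (0.0942), fscn2a (0.0848) and cplx4a (0.0570) were lost without wild-type replicate 3, and those of rp2 (0.0732), prph2a (0.0568) and prph2l (0.0645) without mutant replicate 2.

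Cell cycle genes were higher in the mutants. The cyclin ccnd1 rose from 378 ± 47.9 to 1586 ± 438 (log2 change 2.04, SE 0.22, adjusted p = 0.0133). The mitotic kinase cdk1 rose from 69.6 ± 10.6 to 329 ± 118, the kinase aurkb from 67.9 ± 4.33 to 322 ± 124 and the ubiquitin-conjugating enzyme ube2c from 35.4 ± 9.96 to 173 ± 60.6. The list had a median log2 change of 1.57 over 32 genes, 31 of them positive (camera, adjusted p = 2.08e-16; adjusted p = 0.314 with an estimated correlation). Of these 10 rose over all genes tested and 24 when adjusted over the list alone. Relative to the mean of all libraries, the list stood at 1.12, 0.14 and 0.84 on the log2 scale in mutant replicates 1, 2 and 3, and between -0.82 and -0.62 in wild type. Outside this list, and placed here only after their values were seen, the condensin subunit ncapg2, the passenger complex subunit cdca8, knstrn of the kinetochore, gtse1, the histone methyltransferase setd8b and znf367 rose by log2 changes between 2.43 and 2.62. Every named gene call of this paragraph was lost without wild-type replicate 2 (ccnd1, adjusted p = 0.0778) and without mutant replicate 3 (ccnd1, 0.103; setd8b, 0.217). All but that of ccnd1 were also lost without mutant replicate 1 (cdk1, 0.131) and without wild-type replicate 3 (cdk1, 0.0780). Without mutant replicate 2 those of setd8b (0.0671), ncapg2 (0.0519) and znf367 (0.0506) were lost, and without wild-type replicate 1 that of setd8b (0.0669).

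Genes of reactive glia and regeneration were higher as a list (camera, adjusted p = 0.000754; adjusted p = 0.50 with an estimated correlation and 0.136 with fry; median log2 change 0.32), and 3 of 26 rose, also when adjusted over the list alone. These were neurogenic factors, namely insm1a (264 ± 34.2 to 1300 ± 382, log2 change 2.26, adjusted p = 0.0133), sox11b (876 ± 82.4 to 2544 ± 537, log2 change 1.52, adjusted p = 0.0133) and the proneural ascl1a (109 ± 32.6 to 317 ± 74.4, log2 change 1.55, adjusted p = 0.0408). Müller glia genes were higher by a median of 0.18 on the log2 scale (camera, adjusted p = 0.00407; adjusted p = 0.314 with an estimated correlation and 0.0703 with fry). The genotypes overlapped in this list. Relative to the mean of all libraries it stood at -0.11, 0.054 and -0.24 in wild-type replicates 1, 2 and 3 and at 0.12, 0.16 and 0.018 in the mutants. Of its 27 genes, crabp1a (1824 ± 95.7 to 2844 ± 74.7) and icn (1616 ± 353 to 3839 ± 807) rose, and 7 were higher and 1 lower when adjusted over the list alone. The call of the Müller list was lost without wild-type replicate 3 (adjusted p = 0.0874), and with library totals as the scaling both it (0.0627) and the regeneration list (0.0820) were lost. Retinal ganglion cell genes were higher as a list (camera, adjusted p = 7.11e-07; adjusted p = 0.398 with an estimated correlation and 0.102 with fry; median log2 change 0.75), though none of 19 passed over all genes and 14 did when adjusted over the list alone. Examples were the stathmins stmn2b (2294 ± 407 and 3707 ± 213) and stmn2a (1415 ± 332 and 2338 ± 82.4) and atoh7 (50.4 ± 15.9 and 122 ± 25.6), a proneural factor of retinal progenitors. The calls of insm1a, sox11b, ascl1a, crabp1a and icn were lost without wild-type replicate 2 (insm1a, adjusted p = 0.0778) and without mutant replicate 3 (insm1a, 0.101; ascl1a, 0.180). Without mutant replicate 1 all of these but sox11b were lost (insm1a, 0.0677), and without wild-type replicate 3 those of ascl1a (0.0936), crabp1a (0.0697) and icn (0.0905). The calls of ascl1a and icn were also lost without wild-type replicate 1 (0.0523 and 0.0534) and mutant replicate 2 (0.0546 and 0.0520).

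**Figure D2:**
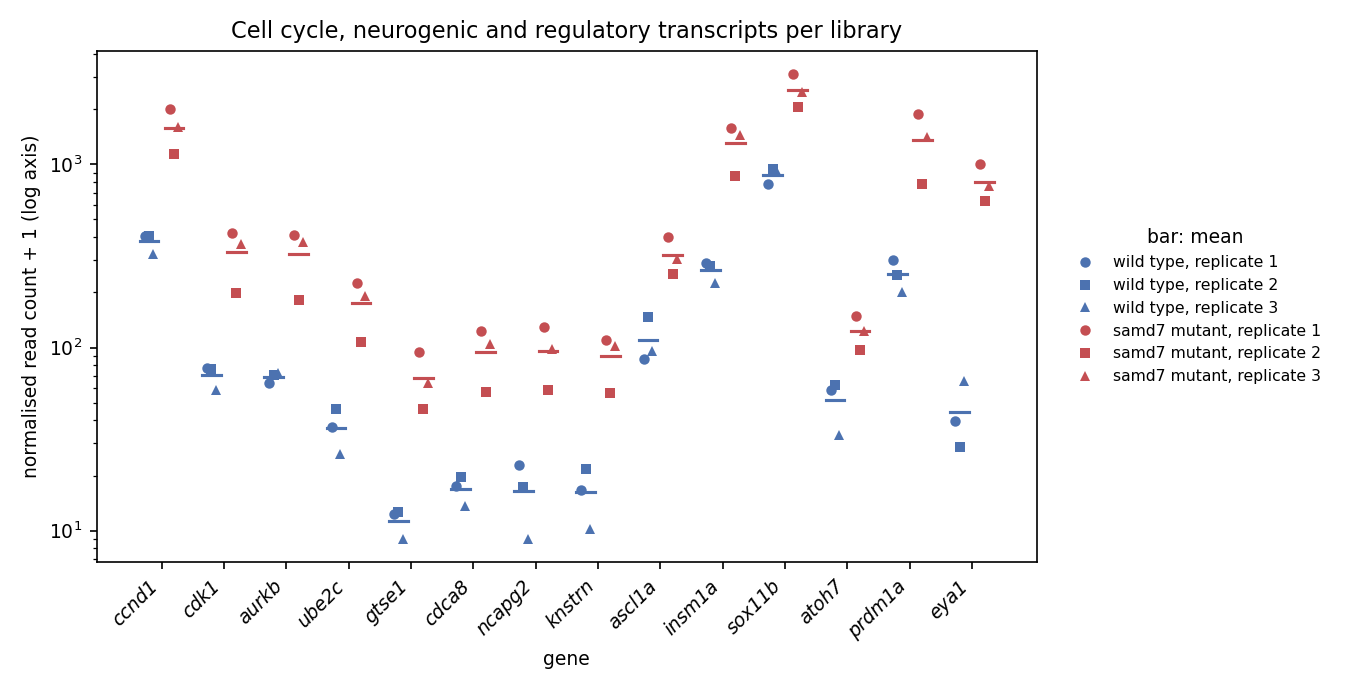
Normalised read count plus 1 (log axis) of cell cycle genes of the fixed list (ccnd1, cdk1, aurkb, ube2c), genes placed with them after their values were seen (gtse1, cdca8, ncapg2, knstrn), neurogenic factors (ascl1a, insm1a, sox11b, atoh7) and the regulators prdm1a and eya1 in each library, with bars for the means of 3 fish. Every mutant lies above every wild-type fish for each of the 14 genes, and atoh7 did not pass the test over all genes. For gtse1, cdca8, ncapg2, knstrn, prdm1a and eya1 the rule that named them required this lack of overlap. The other genes were named for having the smallest p of their lists, which also favours it.

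Other genes with large rises were exorh, cldn11a, myom1a, eya1 and fabp11a. The pineal opsin exorh rose 76.5-fold from 6.19 ± 3.78 to 474 ± 134 (log2 change 6.12, SE 0.42, adjusted p = 0.00324). The claudin cldn11a rose 42.9-fold to 529 ± 184, the sarcomere gene myom1a 26.7-fold to 201 ± 72.1, and eya1, a co-activator of sensory organ development, 18.3-fold to 799 ± 193. The calls of exorh, cldn11a and eya1 held without each library in turn (adjusted p up to 0.0439). Those of myom1a and fabp11a were lost without mutant replicate 3 (adjusted p = 0.153 and 0.178), mutant replicate 1 (0.0960 and 0.158) or wild-type replicate 3 (0.0753 and 0.0912), that of myom1a also without mutant replicate 2 (0.0576) and that of fabp11a without wild-type replicate 2 (0.0524).

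Further large falls were those of dgat2, an enzyme of triglyceride synthesis (70.9 ± 39.7 to 4.67 ± 0.804), nptx2b, a neuronal pentraxin (206 ± 32.7 to 21.5 ± 9.60), lrit3b (219 ± 75.5 to 26.1 ± 16.2), enpep, an aminopeptidase (73.8 ± 21.5 to 10.7 ± 5.87) and bbox1, an enzyme of carnitine synthesis (596 ± 270 to 92.0 ± 24.7). Their adjusted p was between 0.0131 and 0.0446. Without wild-type replicate 2 the calls of nptx2b (0.0778), lrit3b (0.125), enpep (0.143) and bbox1 (0.0820) were lost, as they were without mutant replicate 1 (up to 0.158 for enpep). Without mutant replicate 3 those of dgat2 (0.178), nptx2b (0.0547), enpep (0.147) and bbox1 (0.131) were lost, and without wild-type replicate 3 those of lrit3b (0.0892) and enpep (0.0892). The call of enpep was lost without each of the 6 libraries in turn, that of lrit3b also without mutant replicate 2 (0.0640), and dgat2 was not tested without a wild-type library and was lost without any mutant library.

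Among 18 tested non-visual opsins, exorh rose, the melanopsin opn4.1 fell (log2 change -1.77, adjusted p = 0.0230) and so did zgc:158340, listed as a synonym of opn6a (-1.59, adjusted p = 0.0200). The list had no common direction (camera, adjusted p = 0.379), and 1 rose and 3 fell when adjusted over the list alone. With library totals as the scaling this list was called (adjusted p = 0.0119). The calls of opn4.1 and zgc:158340 were lost without wild-type replicate 2 (adjusted p = 0.0923 and 0.0960), mutant replicate 1 (0.105 and 0.0870) or mutant replicate 3 (0.123 and 0.103).

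Circadian clock genes were lower as a list (camera, adjusted p = 0.00908; adjusted p = 0.314 with an estimated correlation and 0.0844 with fry; median log2 change -0.47). With library totals as the scaling camera still called the list, but its median was -0.12, with 16 genes positive in place of 12. Of 37 the kinase gene camk1gb fell (log2 change -0.86, adjusted p = 0.0363), also when adjusted over the list alone. This call was lost without wild-type replicate 2 (0.129), wild-type replicate 3 (0.0892), mutant replicate 1 (0.158) or mutant replicate 3 (0.178). The clock genes per2, cry1b and cry1a had log2 changes of -0.40, -0.67 and -0.75 and did not pass. Libraries of the same genotype differed far more in other clock genes, chosen after their values were seen. For example per1b was at 12506, 5112 and 2494 in wild-type replicates 1, 2 and 3 and at 4126, 2797 and 894 in the mutants. The repressor nr1d1 was at 5588, 511 and 68.9 against 784, 203 and 43.2. For both genes replicate 1 was the highest and replicate 3 the lowest in both genotypes.

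**Figure D3:**
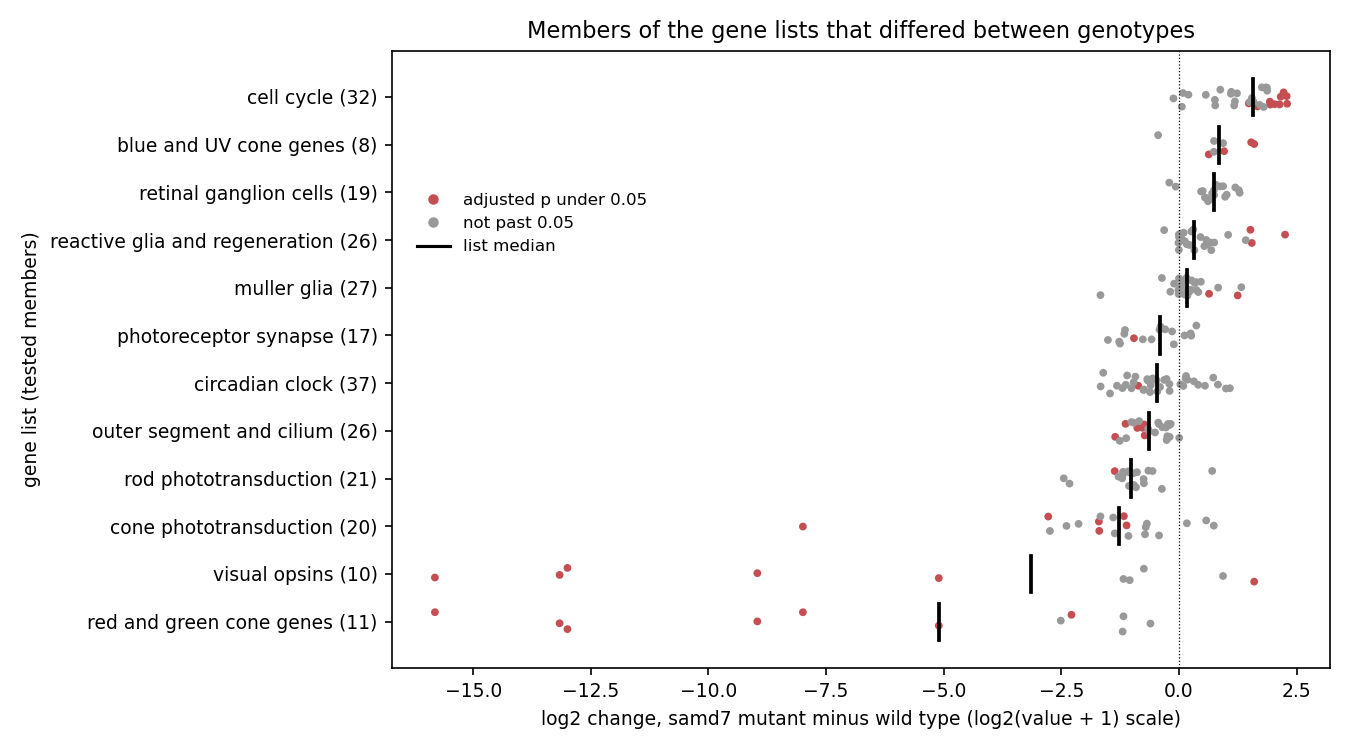
Log2 change (mutant minus wild type, log2(value + 1) scale) of each tested member of the 12 gene lists called by camera with a preset correlation, with black bars for the list medians and red for genes past an adjusted p of 0.05. Red and green cone genes lie farthest to the left with a median of -5.10, cell cycle genes farthest to the right with a median of 1.57, and the point of opn1mw1 is a fitted value, not a bound.

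Amacrine, bipolar and horizontal cell genes did not move as lists. Bipolar cell (adjusted p = 0.558), horizontal cell (0.321) and amacrine cell genes (0.121) were not called by camera and held no gene past the threshold. Adjusted over the list alone, 4 horizontal cell genes, 1 bipolar gene and no amacrine gene were lower. Without wild-type replicate 1 the amacrine list was called higher (adjusted p = 0.000343). Pineal genes were not called (0.702), and exorh was the one member that rose, by either adjustment. Visual cycle genes (0.242), Polycomb subunits (0.487), p53 and cell death genes (0.609) and heat shock and unfolded protein genes (0.558) were not called and had no member past the threshold by either adjustment. With library totals as the scaling the visual cycle list was called (0.0305). Median, mean and test differed in sign for bipolar genes (median 0.13, mean -0.0076, tested as higher) and heat shock genes (0.13, -0.0053, higher).

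Of 32 tested homeobox and T-box factors outside photoreceptors, pax2b rose from 77.3 ± 11.8 to 162 ± 14.0 (adjusted p = 0.0442), the one gene to do so by either adjustment. Its call was lost without each library in turn (adjusted p from 0.0570 to 0.178). The list was not called (camera, adjusted p = 0.139), but was called higher without mutant replicate 3 (0.0224). Among 48 hox genes only 2 reached the filter, too few for a list test. The summed normalised read count of all 48 was 80.6 ± 46.3 in wild type and 49.4 ± 21.1 in the mutants (exact permutation test, two-sided, p = 0.4).

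Markers of tissues that a dissected retina can carry did not move with the genotype as lists. The adjusted p from camera was 0.878 for pigment epithelium, 0.558 for microglia and leukocytes, 0.558 for complement and interferon genes, 0.791 for blood vessel and 0.518 for erythrocytes. It was 0.215 for lens, 0.628 for oligodendrocytes and myelin, 0.322 for cornea and skin and 0.929 for muscle. Of their 148 entries 1 rose, mpzl2b of the oligodendrocyte and myelin list (534 ± 7.96 to 875 ± 100), by either adjustment, and none fell. That call was lost without mutant replicate 3 (adjusted p = 0.164) and without each other library but wild-type replicate 1. For oligodendrocytes (median -0.0049, mean 0.078, tested as higher) and muscle (0.057, -0.040, tested as lower) the median and the test differed in sign. With library totals as the scaling the erythrocyte list was called (0.00231). Relative to the mean of all libraries, the complement and interferon genes were higher by 1.46 on the log2 scale in wild-type replicate 2. Without that library this list and that of microglia and leukocytes were called higher in the mutants (adjusted p = 1.90e-05 and 0.000128). Pigment epithelium genes were at -0.96 in wild-type replicate 1 and -1.17 in mutant replicate 2.

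Very few genes were near 0 in one genotype and expressed in the other. With under 0.1 CPM in every library of one genotype and over 1 CPM in every library of the other, opn1mw1 and opn1mw3 were off in the mutants, and mnx2a, a homeobox gene, was off in wild type. The latter was at 0.583 ± 1.01 in wild type and 32.7 ± 6.81 in the mutants (adjusted p = 0.0244), lost without wild-type replicate 2 (0.0890) or 3 (0.0583) and not tested without a mutant library.

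In all, 296 of 11335 genes passed an adjusted p of 0.05, 94 higher and 202 lower in the mutants, and 157 of them differed at least 2-fold (68 higher, 89 lower). The genotypes did not overlap for 3186 genes, 28.1% of those tested, where chance gives 10% on average. Genes move together, so a single grouping can lie far from that average, and the share was not computed for other groupings. The count moved with single libraries. It was 17 without wild-type replicate 2, 69 without wild-type replicate 3, 29 without mutant replicate 1, 23 without mutant replicate 3, 247 without mutant replicate 2 and 366 without wild-type replicate 1. Scaled to library totals alone, 2128 genes passed, 1987 higher and 141 lower, or 6.63% lower in place of 68.2%. That scaling moved the median of all genes to 0.36 on the log2 scale, against 0.013 with the deposited size factors, to which the changes given here are relative. In the authors' deposited table, 1182 of 11609 genes had an adjusted p under 0.05, 451 higher and 731 lower, and all 296 genes called here were among them with the same sign.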

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

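The edgeR alternatives were chosen after the data had been seen, and the others before. Against 296 genes in the main test (94 higher, 202 lower), library totals gave 2128 (1987 higher), since that scaling shifts all genes towards the mutants. Upper-quartile scaling gave 129 lower genes. Limma without trend gave 30 (8 higher, 22 lower), voom 130 (37, 93) and DESeq2 1184 (450, 734), and the cause was not tested. A change of at least 2-fold left 157 genes, 89 of them lower, and an adjusted p of 0.01 left 23 (4 higher, 19 lower), as fewer genes meet a stricter threshold. Median-ratio factors, TMM, no filter, a stricter filter, both pseudocounts and edgeR gave 255 to 312 genes. With one library left out in turn, with fewer samples, the count was 17 to 366 (4 to 130 higher, 11 to 236 lower). With the replicate number as a replicate block, 289 genes passed, 195 of them shared with the main test, and opn1sw2 passed (adjusted p = 0.0431). The replicate numbers did not pair the libraries over all genes, as deviations from the genotype means correlated across genes at 0.19, -0.14 and 0.23 for equal numbers, though clock genes, looked at after the results were seen, gave 0.78, -0.15 and 0.93.

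Of the 12 gene lists called by camera, 0 were called with an estimated correlation (lowest adjusted p = 0.0852) and fry called 6. Fry lost those of rod (0.246), regeneration (0.136), synapse (0.112), ganglion cell (0.102), clock (0.0844) and Müller glia (0.0703) genes, and the cause was not tested. The gene calls by the naming rule covered 25 genes and 478 values over all alternatives, of which 376 stayed past the threshold, 102 were lost and 0 changed sign. With one library left out in turn, 9 of these genes passed in each fit that tested them, of which opn1mw1, opn1mw3 and opn1mw4 were tested only in the 3 fits without a mutant library. The highest adjusted p of the others was 0.217. Of 702 list values over all alternatives 672 kept their side of the threshold. Direction was compared only where a list was called in the main test or in the alternative. It could turn in lists called in neither. The median log2 change of complement and interferon genes, for example, was 0.20 with all libraries and -0.24 without wild-type replicate 3. The share of rhol among visual opsins, -0.063 percentage points in the main comparison, was between -0.15 and 0.0111 with one library left out, the latter without wild-type replicate 3. For genes near zero, against 1 near zero in wild type and 2 in the mutants, halving the floor gave 0 and 1, and doubling the floor gave 0 near zero in wild type. Opsin shares by transcript length were not run, since lengths of the build used are not given in the sources used here. The depth of 20186266 to 29117026 reads limits what can be said of genes with a few reads, such as opn1mw3 in the mutants.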

Other observations

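The lists of metabolic and of neurogenic genes, and the tests on summed tandem opsins, on exorh against rho, on pineal genes, on markers of other tissues with and without single libraries, on markers of other retinal cell classes and on the clock genes of equally numbered libraries, were chosen after the results they concern had been seen. Genes of glycolysis and the citric acid cycle were lower in the mutants, with a median log2 change of -0.32 over 50 genes (camera p = 3.25e-11; p = 0.0696 with an estimated correlation). The list was prompted by the called genes mdh1ab, ppa1a and ppa1b, of which only mdh1ab was among its 50 genes. Without mdh1ab the camera p was 1.64e-10, and 0.0734 with an estimated correlation. The malate dehydrogenase gene mdh1ab fell from 28781 ± 2097 to 10882 ± 1353 (adjusted p = 0.00749), and pdha1b, sdhdb and got2a fell too (adjusted p up to 0.0422 for got2a). Scaled to library totals the median of the list was 0.033, so the fall is relative to the other genes. Without wild-type replicate 2 the calls of all 4 genes were lost (mdh1ab, adjusted p = 0.0651), and without mutant replicate 1 or 3 those of pdha1b (0.132 and 0.153), sdhdb (0.149 and 0.169) and got2a (0.163 and 0.178). Without wild-type replicate 3 those of sdhdb (0.0583) and got2a (0.0998) were lost, and that of got2a also without wild-type replicate 1 (0.0511) or mutant replicate 2 (0.0826).

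A list of Notch pathway and neurogenic genes was higher, with a median log2 change of 0.55 over 37 genes, 28 of them positive (camera p = 6.28e-07; p = 0.0538 with an estimated correlation). Without dld and ascl1a, which had prompted the list, and without genes of the regeneration list, the median was 0.30 and p was 0.000574 over 30 genes, and 0.0592 with an estimated correlation. The Notch ligand dld rose from 29.9 ± 9.39 to 89.7 ± 7.49 and the corepressor gene rcor2 from 176 ± 22.2 to 399 ± 45.2, next to sox11b, insm1a and ascl1a. These 5 were the members that passed. No Notch receptor passed, and neither did the her, hes and hey genes, which went both ways, with hes2.2 (1.46), hes6 (0.83) and her9 (0.37) positive, her4.2 (-0.62), her15.1 (-0.41) and hey1 (-0.27) negative, and her6 (-0.10) and hey2 (-0.046) near 0. Whether Notch signalling changed stays open. Without wild-type replicate 2, mutant replicate 1 or mutant replicate 3 the calls of dld (adjusted p = 0.115, 0.177 and 0.216) and rcor2 (0.0984, 0.127 and 0.148) were lost, and that of dld also without wild-type replicate 3 (0.0936) or mutant replicate 2 (0.0976).

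The shift of opsins was set against 5 technical explanations. The values argue against each, except pineal tissue as a source of exorh and the division of reads between tandem copies, which stay open. Reads shared between tandem copies would leave the sums in place, but the summed green opsins changed by -13.64 on the log2 scale and the summed red opsins by -2.31. Sharing thus did not make the fall of the sums. How reads were divided between copies, such as opn1lw1 and opn1lw2, is not settled by the sums. Reads of rho counted at exorh would keep their ratio, which rose by 7.43. Pineal tissue would raise the other pineal genes, whose median over 8 genes was -0.30. This cannot decide, since a small share of pineal tissue could stay hidden in genes that wild-type retina already expresses. For example, asmt2 was at 389, 924 and 997 in wild type, while exorh reached 474 in the mutants. The scaling would have to remove the rise of opn1sw1, whose lowest log2 change over 5 scalings was 1.60. A candidate explanation is the loss of samd7 itself, a hypothesis from the same data, while an allele linked to the mutation stays open as untested, and a second allele or a rescue, not analysed here, would be needed to decide between them.

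Of 3 explanations for the rise of cell cycle genes, the first was dividing cells of another tissue. Many such cells would raise the markers of that tissue as well. The median of 72 leukocyte, vessel, cornea and lens markers was 0.124 (-0.0068 to 0.272), against 1.57 (1.18 to 1.83) for the cell cycle list. This cannot decide, since a small share of dividing cells could stay hidden in markers that wild-type libraries already hold. Ranges in brackets in this paragraph are 95% bootstrap ranges over the genes of a list, with the same fish throughout. They treat genes as independent and leave out the spread between fish, so they do not test the genotype difference. In wild-type replicate 2 leukocyte genes were higher by 0.71 on the log2 scale than the mean of all libraries. Without that library the median of the 72 markers became 0.289 (0.144 to 0.402), against 1.59 (1.25 to 1.94) for the cell cycle list. That of leukocyte genes, then called higher by camera (adjusted p = 0.000128), was 0.401 (0.189 to 0.816). Complement and interferon genes, a list not among these markers, were nearer to the cell cycle list, at 1.04 (0.757 to 1.19). Lens genes alone were at 0.683 (0.00971 to 1.36) against 1.44 (1.12 to 1.74) without wild-type replicate 3. Their range overlapped that of the cell cycle list there and without mutant replicate 1 (medians 0.688 and 1.26). A lower share of photoreceptor RNA would raise the markers of all other retinal classes alike and by as much, but their median over 102 genes was 0.219 (0.15 to 0.28), and ganglion cell genes at 0.75 (0.58 to 0.94) moved apart from Müller glia genes at 0.18 (0.047 to 0.33) and bipolar genes at 0.13 (-0.054 to 0.24). One mutant library alone was not the source, as the lowest median without a library was 1.26, without mutant replicate 1, with a lower bound of 0.933. More dividing cells in the mutant retina, more transcripts per cell or a small share of dividing cells of another tissue may underlie the rise. No value here separates them, and the rise of ganglion cell genes stays open.

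Wild-type replicate 1 stood farthest from the others of its genotype, with 129 genes at least 2-fold higher and 215 lower among genes of at least 5 CPM on which the other 2 were close, against at most 54 higher and 60 lower for any other library. Depth is argued against, since the gap in correlation was 0.0136 before and 0.0138 after thinning to equal reads. The gap was 0.0132 without 200 genes of pigment epithelium, blood and lens or following them, so those genes alone did not make it. A difference in tissue carried over stays open, since pigment epithelium genes stood at -0.96 in this library relative to the mean of all libraries. For example, rgrb was at 2078 against 11344 and 11744 in wild-type replicates 2 and 3. Clock phase at dissection may contribute, as the median distance of 37 clock genes was 1.75 on the log2 scale (from 0.302 to 1.33 for the other libraries), at percentile 100 of 10000 random lists matched on expression (median 0.218, 95th percentile 0.314). The clock genes were not particular to this library, since deviations from the genotype mean, correlated across these 37 genes, which are not independent replicates, were at 0.78 between both replicates 1 and 0.93 between both replicates 3, but at -0.15 between both replicates 2, and guca1e was low in both replicates 1 (49.9 and 116). A shared time or day of dissection for equal numbers stays open, as neither is given in the sources used here.

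Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes, the real one with 296 against at most 0 in the others. As many gene lists were called in 2 splits, the real one with 12 and that of wild-type replicate 1 with mutant replicates 1 and 2 with 13. Each of the other splits called lists too, from 1 to 11 of them. The number of lists called with the preset correlation thus does not set the genotypes apart from other groupings. As many genes near zero were found in 1 split, the real one with 3 against at most 1. The splits are too few for a share under 0.05.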
